A study of Rattus norvegicus with 156 samples.

How the data were processed

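RNA was measured on Affymetrix rat U34 arrays, a set of 3 arrays (A, B and C) that carry different probe sets. The 156 arrays came from 52 RNA samples, each hybridised to all 3 arrays, and the 3 arrays of a sample were joined. Each sample was 1 RNA pool from 4 to 6 rats of 1 treatment and 1 tissue. The treatments were naive, naive with gabapentin, sham surgery, spinal nerve ligation (SNL), and SNL with gabapentin, called the 5 pools here. The pools covered up to 11 tissue and side combinations, called compartments here: dorsal root ganglia (DRG) of levels L4 to L6, sciatic nerve and spinal cord of each side, and brain. The naive L6 DRG of the contralateral side, the naive gabapentin L5 DRG of the contralateral side and the SNL sciatic nerve of the contralateral side were not among the samples used here. Other organs of naive rats that the study describes were not analysed here.

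The values are linear probe set intensity as deposited, made with MAS5 per the labels, whose version, scaling target and detection calls are not given in the sources used here. Column medians ranged from 13 to 62.2 on array A, from 8.1 to 47.2 on B and from 14.5 to 53.3 on C. The 2% trimmed means of the arrays of a set differed by 4.10-fold on A, 4.66-fold on B and 2.98-fold on C. A rule set beforehand called for scaling where this exceeded 1.25-fold, so the arrays of each set and compartment were quantile normalized. The deposited scaling was kept as an alternative. Values were taken as log2 of signal plus a pseudocount, the 20th percentile of all values of a set (5.8 for A, 4.5 for B and 6.2 for C). Folds are on that scale and are smaller than ratios of signals for weak genes. Probe sets were kept if their signal passed the 40th percentile of its array in at least 2 samples of a comparison, and control probe sets were left out.

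Of 26379 probe sets, 177 were controls, 18178 carried 1 gene symbol, 391 carried several and 7633 none. Symbols were updated through Entrez gene identifiers for 18122 probe sets with a RefSeq gene table of the GRCr8 assembly, used for names only, which gave 10969 distinct symbols. Each gene is represented by its probe set with the highest mean log2 value over all samples. Genes are named by symbol, since the probe set identifiers are sequence accessions. Cacna2d2 had no probe set among those with a single symbol.

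Each treatment had 1 pool per compartment, so treatments had no replicates and no paired analysis of treatments was possible. The ligated pools (SNL, SNL with gabapentin) were compared with those not ligated (naive, naive with gabapentin, sham), 2 against 3, or 2 against 2 in the contralateral L5 and L6 DRG. Each group holds 1 pool with gabapentin, except in the contralateral L5 DRG. There the unligated pools were naive and sham, so the drug is unbalanced in that comparison and in the L5 difference between sides. Both ligated pools had surgery but only 1 of the 3 others did, so an effect of surgery itself falls partly in the ligation change. Tests used limma 3.58.1 (lmFit, eBayes with a mean-variance trend) in R 4.3.3, fitted per compartment, two-sided. P values were adjusted by the Benjamini-Hochberg method over all kept probe sets of the 3 arrays, with a threshold of 0.05. Differences between compartments were tested on the difference of log2 values of the same treatment. Whether the same rats gave both tissues is not given in the sources used here. Gabapentin was tested with ligation as a covariate, 2 pools against 3, in L5 DRG, sciatic nerve and spinal cord, and on each pool's mean over the 8 compartments in which all 5 pools were measured. Among 2 against 3 samples, chance alone separates the groups fully in 20% of probe sets, and among 2 against 2 in 33.3%. The number of pools limits the precision of every value. Values are given as log2 change or fold with the standard error (SE) of the fit, and signals as mean ± SD over pools.

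For gene groups, 31 lists with 729 entries were fixed before the data were examined, as were the comparisons, the tests, the threshold and the rule for named genes. The arrays measured 623 entries, and 32 of the 35 genes of the complement list. Lists were tested with camera of limma against all other genes at a preset correlation of 0.01, adjusted within 299 ligation tests, 90 tests of differences between compartments and 120 gabapentin tests. Of these, 61, 30 and 11 passed. With a correlation estimated per list, 0 passed in each family, and the lowest adjusted p values were 0.631, 0.411 and 0.988. Unadjusted p with an estimated correlation was below 0.05 for 23, 8 and 0 lists. Every list call in the text therefore rests on the preset correlation. Counts of list members that passed are given over all probe sets tested and, in those words, adjusted over the list alone.

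Named genes follow a fixed rule. It takes the 10 largest rises and 10 largest falls among genes past the threshold whose groups do not overlap, up to 4 members of each list past the threshold with the largest change, and all measured complement genes in L5 and L6 DRG, sciatic nerve and spinal cord. It adds Cacna2d1 in every comparison and, where fewer than 5 genes pass, the 5 with the smallest p in each direction, said not to have passed. For each tissue it also takes the 3 highest markers of neurons, myelin, astrocytes and muscle. A few further list members are named beside their list's count and were chosen after their values were seen.

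The fit was tested on simulated values drawn around the mean of each probe set with the spread fitted to these arrays, with 100 probe sets changed 2-fold and 100 changed 4-fold. The L5 DRG comparison recovered 46% of the former and 92% of the latter, the sciatic nerve 1% and 70%, and the spinal cord 21% and 69%, with false shares among calls of 7.38%, 8.97% and 6.25%. With no change added, 0 calls were made. Each probe set was drawn independently, so variation shared by many genes of a pool was not simulated. The false shares may therefore differ in the real pools. The 3' to 5' signal ratio of the GAPDH control probe sets served as a measure of RNA integrity. Printed ratios are means over the 3 arrays of a sample, and the covariate was the mean of their log2 values. All 52 samples had their best-correlated array from the same tissue on each set, and 0 arrays were identical.

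The alternatives tried were a pseudocount at the 5th percentile or the median, no filter on low signals, the deposited scaling, variance without a trend, gabapentin as a covariate, 1 spread shared over compartments, leaving out each pool in turn, an estimated correlation for the lists, and lists over all probe sets of their genes. Added after the data were seen were median scaling, the nerve without the naive and sham pools, the GAPDH ratio as a covariate, and the skeletal muscle markers as a covariate.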

Results

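Gene expression was measured in the nervous system of rats with ligated L5 and L6 spinal nerves, a model of neuropathic pain, 19 to 21 days after surgery. Sham surgery exposed these nerves without tying them. Gabapentin (GPN), an antiepileptic drug used against neuropathic pain, was given at 100 mg per kg on each of 7 days, and other rats received vehicle. Ligated rats were included after tests of paw withdrawal on days 12 to 14. Each group had 8 to 12 rats, split for each tissue into 2 pools, of which the first was arrayed. The 5 pools were naive, naive with GPN, sham, SNL and SNL with GPN, each of 4 to 6 rats, and there were 52 samples over 11 compartments. DRG hold the cell bodies of sensory neurons; those of L5 and L6 send their axons through the ligated nerves, while those of L4 send theirs through an intact spinal nerve. The sciatic nerve was taken at mid thigh, beyond the ligation, and the spinal cord was divided by side. In naive rats the side is a label only. Whether the arrayed pool held the same rats in every tissue is not given in the sources used here, so compartments are not taken as independent of each other.

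The tissues carried the transcripts of their main cells. In the 3 L5 DRG pools without ligation, the neurofilament gene Nefl stood at 154 ± 9.77 (SD, n = 3) times the array median and the Schwann cell myelin gene Pmp22 at 185 ± 17.6 times. The corresponding sciatic nerves held Pmp22 at 369 ± 48.6 times and Mbp, a myelin protein gene, at 270 ± 25.3 times. Nerves also held the skeletal muscle genes Ckm at 147 ± 65.0 times and Acta1 at 131 ± 41.7 times, so muscle lay in these samples. Mbp reached 159 ± 39.1 times in spinal cord and 172 ± 23.0 times in brain, where the neuronal enolase Eno2 stood at 68.3 ± 6.60 times.

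What ligation changed in ganglia whose own nerve was tied was asked first in the ipsilateral L5 DRG. The neuropeptides Vip, Npy and Gal rose by 20.7-fold, 20.1-fold and 11.5-fold, the largest rises on the log2 scale with its pseudocount. Vip signal was 321.2 ± 53.2 (n = 2) in ligated pools against 11.8 ± 11.4 (n = 3) in the others, with a log2 change of 4.37 (SE 0.46, adjusted p = 0.00219). Npy signal was 2006 ± 231 against 111 ± 83.1, and Gal 842 ± 45.7 against 77.2 ± 49.6. Atf3, a transcription factor gene induced by axon injury, rose 6.85-fold (SE of log2 0.27, adjusted p = 0.00172), from 71.3 ± 27.8 to 500.4 ± 21.8. Falls included Dpysl4 (by 3.47 on the log2 scale), the potassium channel subunits Kcns1 (9.65-fold) and Kcnd3 (7.99-fold), and Scn11a, a sodium channel of nociceptors, which went from 639 ± 43.1 to 99.9 ± 10.2.

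Among all kept probe sets, 2617 of 16746 passed, 1130 higher and 1487 lower, standing for 583 and 813 genes. Array B medians before normalization were 23 in SNL and 18.1 in SNL with GPN. They were 29.2 in naive, 27.4 in naive with GPN and 25.6 in sham. Brightness and ligation therefore cannot be told apart for probe sets of array B, among them those of C1qa and C2. On arrays A and C the medians of the groups overlapped. In all 2617 that passed both ligated pools lay beyond all 3 others. Passing with so few pools nearly requires this, so it adds nothing to the calls. Of all probe sets 49.5% had groups apart where chance gives 20%. Other large rises were Reg3b (log2 change 3.27), a secreted lectin, the chemokine Cxcl14 (3.13), Kif22 (2.95), the cytokine Tslp (2.83) and the protease inhibitor Slpi (2.79). The unligated signals of Reg3b (5.90), Tslp (2.27) and Slpi (4.63) lay near or below the pseudocount, which keeps their folds below the ratio of signals, so they cannot be ranked against Npy or Gal. Other large falls were Ifitm10 (-3.10), Rnf112 (-2.63), Tesc (-2.56), the peptide somatostatin (Sst, -2.49), Lin7b (-2.49) and the sodium channel Scn1a (-2.31). The ligated signals of Kcnd3 (3.48) and Lin7b (2.41) lay below the pseudocount, so their place among the falls depends on it.

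Complement, the subject named in the title of the series, is a cascade of plasma and tissue proteins that tags and lyses targets. Of 32 complement genes on the arrays, 20 passed the signal filter in L5 DRG and were tested, of which 10 rose and 0 fell (12 and 1 adjusted over the list alone). C1qb and C1qa, chains of the recognition molecule C1q, rose 6.39-fold (SE of log2 0.13, adjusted p = 0.000334) and 3.99-fold. C1s (4.58-fold, adjusted p = 0.0249) and C1r (2.58-fold), its proteases, C3 (3.89-fold, adjusted p = 0.00811), the central component, and Serping1 (2.82-fold), the C1 inhibitor, rose too. C1s signal was 611.7 in SNL and 198.8 in SNL with GPN, and its log2 change went from 2.19 to 1.40 without SNL (adjusted p = 0.116); the call was also lost with no filter (adjusted p = 0.055), without naive (0.0655) and without naive with GPN (0.0837). Smaller rises were those of C2 (0.99 on the log2 scale), C4a (0.74), C1qc (0.62) and Cfp (0.50). The tested members that did not pass were Cfd (1.22, adjusted p = 0.0778), Cr1l (0.50), C5ar1 (0.25), Cfi (0.18), Clu (-0.00), Cd59b (-0.05), C6 (-0.08), Masp1 (-0.33), C8g (-0.35) and Cd55 (-0.57, adjusted p = 0.0575). The list had a median of 0.56 and an adjusted p of 0.00019, and adjusted p = 0.69 with an estimated correlation. With no filter on low signals the list median was 0.11 (adjusted p = 0.00923). Over all probe sets of its genes it was 0.42 (adjusted p = 0.00462). The size of the median therefore depends on the filter.

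Other immune lists rose in L5 DRG. Of 11 genes of MHC class II presentation 9 rose (10 adjusted over the list alone; median 1.81, adjusted p = 1.27e-08, adjusted p = 0.69 with an estimated correlation), led by Cd74 (8.77-fold; 1535 ± 169 against 188 ± 108), the invariant chain, and RT1-Ba (5.71-fold). Macrophage markers rose in 13 of 19 (14 adjusted over the list alone), among them Gpnmb (2.14), the lysozyme Lyz2 (1.80), Laptm5 (1.62) and Fcer1g (1.49), with a median of 1.14, adjusted p = 1.27e-08, and adjusted p = 0.631 with an estimated correlation. MHC class I presentation had 3 rises among 15 genes (7 adjusted over the list alone; median 0.38, adjusted p = 0.00353, adjusted p = 0.69 with an estimated correlation). Cytokines and chemokines had 6 rises and 1 fall among 13 (7 and 1 adjusted over the list alone; median 0.52, adjusted p = 0.0486, adjusted p = 0.664 with an estimated correlation), with Il18 at 1.33 and Cxcl13 at 1.13. The interferon list did not pass, though Gbp2 (1.70) and Mx2 (1.33) rose.

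Genes tied to axon regrowth rose as well: 17 of 28 (18 adjusted over the list alone, which also called 1 fall), with Atf3, Arg1 (2.44), Csrp3 (2.31), Gadd45a (1.70) and the growth cone gene Gap43 (1.20, counted among neuronal markers). This list had a median of 0.71, adjusted p = 9.19e-08, and adjusted p = 0.647 with an estimated correlation. Extracellular matrix genes rose in 15 of 30 (19 adjusted over the list alone; median 0.69, adjusted p = 1.27e-08, adjusted p = 0.631 with an estimated correlation), led by Postn (1.72) and Mgp (1.63). Immediate-early genes rose in 4 of 14 (6 adjusted over the list alone; median 0.44, adjusted p = 0.000236, adjusted p = 0.631 with an estimated correlation), and cell cycle genes in 2 of 16 (6 adjusted over the list alone; median 0.35, adjusted p = 0.0488, adjusted p = 0.715 with an estimated correlation), with Top2a at 0.96. Neuropeptides parted: 4 rose and 7 fell among 15, with a median of -0.65 and a mean of 0.24, and the list did not pass.

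Markers and channels of sensory neurons fell. Of 15 nociceptor markers 10 fell and 1 rose (the same counts adjusted over the list alone), with the sodium channel Scn10a at -1.98, the serotonin receptor Htr3a at -1.91 and the capsaicin receptor Trpv1 at -1.62; the median was -0.71, adjusted p = 6.95e-06, and adjusted p = 0.631 with an estimated correlation. Sodium channels had 5 falls and 1 rise among 9 (6 and 2 adjusted over the list alone; median -0.90, adjusted p = 0.0046, adjusted p = 0.631 with an estimated correlation). Potassium channels had 12 falls and 0 rises among 26 (16 adjusted over the list alone; median -0.63, adjusted p = 1.9e-06, adjusted p = 0.631 with an estimated correlation), including Kcnd1 (-1.63) and Kcnab1 (-1.56). Genes of synaptic vesicles fell in 13 of 23 and 1 rose (15 and 1 adjusted over the list alone; median -0.75, adjusted p = 6.23e-07, adjusted p = 0.631 with an estimated correlation), with Syt2 at -1.68 and Vamp1 at -1.61. Of 20 pan-neuronal markers 9 fell and 1 rose (10 and 1 adjusted over the list alone; median -0.42, adjusted p = 7.65e-05, adjusted p = 0.69 with an estimated correlation), among them Rbfox3 (-1.57) and Nefl (-1.25). In contrast Cacna2d1, the calcium channel subunit to which gabapentin binds, rose 3.60-fold (SE of log2 0.12, adjusted p = 0.000908), from 87.5 ± 6.35 to 329 ± 8.56.

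Further falls in L5 DRG were the glutamate receptor Grik1 (-2.30), the calcium channel Cacna1h (-1.67), the GABA receptor Gabbr2 (-1.19), the receptors Gfra2 (-1.11) and Ngfr (-0.96), and the glial genes Ntsr2 (-1.06), Aldoc (from 1195.5 to 597.7) and Fabp7 (-0.96), while Gabra5 (1.12) and the myelin gene Cldn11 (1.33) rose. Skeletal muscle markers had a median of 0.86 with 0 of 28 past the test, also 0 adjusted over the list alone (list adjusted p = 0.0075, adjusted p = 0.75 with an estimated correlation). Their mean log2 value was 6.94 in naive, 5.72 in naive with GPN, 5.14 in sham, 6.42 in SNL and 7.52 in SNL with GPN. At the deposited scaling, which shifted the median of all genes by -0.25, 3078 probe sets passed, 469 higher and 2609 lower, and at median scaling 2699, 653 higher and 2046 lower. The count was 1368 without naive with GPN, 1565 without sham, 768 without SNL and 1547 without SNL with GPN. The GAPDH 3' to 5' ratio was 1.08 in SNL and 1.16 in SNL with GPN, against 1.18 to 1.32 in the unligated L5 pools. It was also apart in L6 (1.20 and 1.15 against 1.21 to 1.58) and L4 DRG (1.16 and 1.10 against 1.35 to 1.40). The ratio was not fitted as a covariate in DRG, so its part was not tested.

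**Figure D1:**
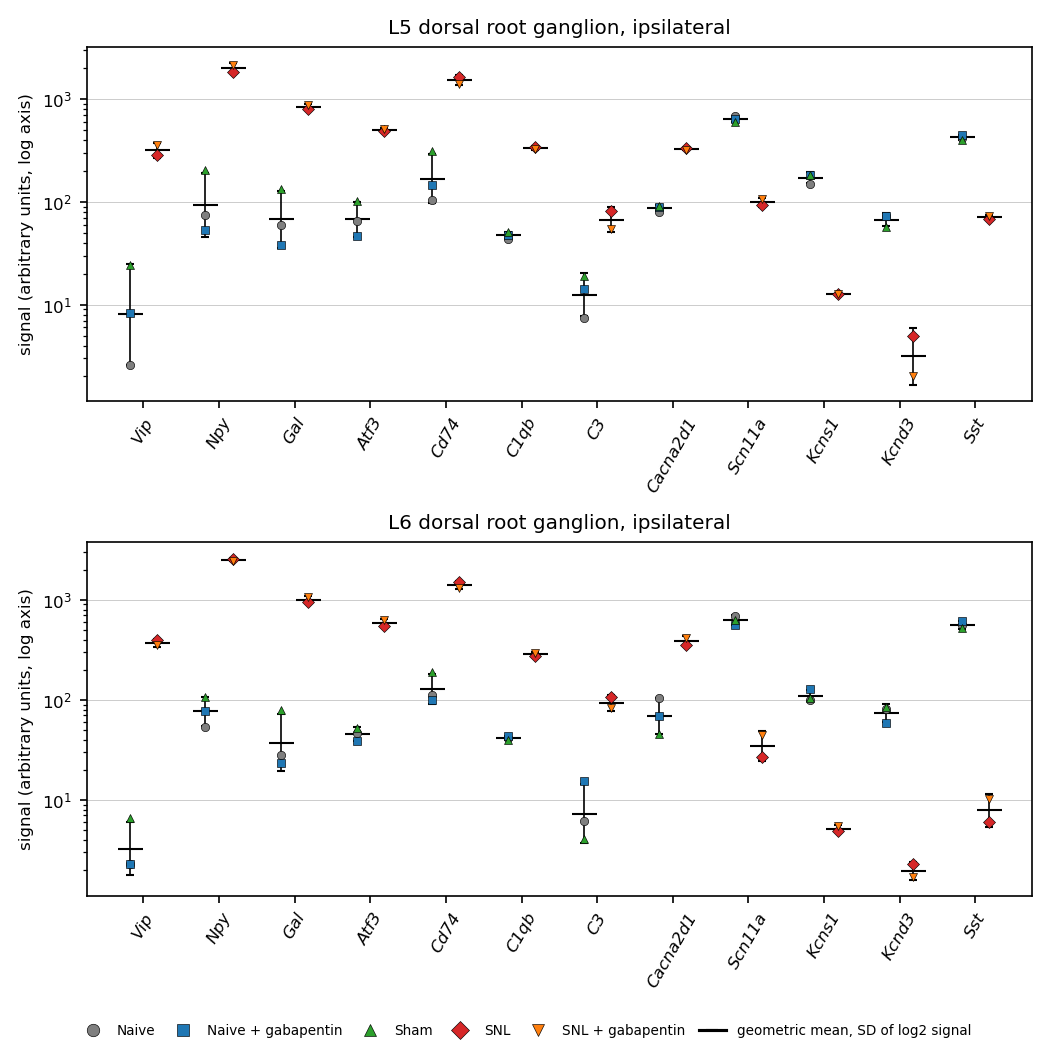
Signal (arbitrary units, log axis) of 12 genes in the L5 and L6 DRG of the ligated side, 1 point per pool, with the geometric mean and the SD of log2 signal of each group (3 pools without ligation, 2 with). Vip signal lay at 283.6 and 358.8 in the ligated L5 pools and at most at 24.5 in the others.

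The ipsilateral L6 DRG, the other ligated level, gave 1451 of 16901 probe sets past the test, 738 higher and 713 lower, for 412 and 400 genes. Vip rose 39.0-fold (SE of log2 0.24, adjusted p = 0.000178), from 3.73 ± 2.51 (n = 3) to 374 ± 32.7 (n = 2), Npy 30.5-fold, Gal 23.1-fold, Atf3 11.6-fold and Csrp3, a muscle LIM protein gene, 10.9-fold. Somatostatin fell 41.1-fold (adjusted p = 7.02e-05), from 562.5 ± 46.7 to 8.17 ± 3.04, and Scn11a 15.7-fold. The low signals of Vip and somatostatin lay near the pseudocount, so their folds are smaller than the ratios of signals. Further rises were those of Cd74 (3.40), Kif22 (3.10), Tslp (2.98), Cdc42se2 (2.97) and Tgm1 (2.95), and further falls those of Grik1 (-3.41), Kcns1 (-3.41), Kcnd3 (-3.36), Dpysl4 (-3.21), Htr3a (-3.21), Ifitm10 (-3.19), Scg2 (-3.12) and Nptx1 (-3.11). The low signals of Tslp (1.84), Tgm1 (3.77), Kcnd3 (1.99), Kcns1 (5.19) and Grik1 (5.80) also lay at or below the pseudocount, so the order of these changes depends on it. Calca, which encodes the peptide CGRP, fell by 2.66 on the log2 scale and the parvalbumin gene Pvalb by 2.64. Cacna2d1 rose 5.22-fold (SE of log2 0.30, adjusted p = 0.00461), from 73.1 ± 29.9 to 388 ± 44.0.

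Complement in L6 DRG had 7 rises and 1 fall among 21 tested genes (10 and 1 adjusted over the list alone). C3 rose by 2.87, C1qb by 2.62, C1qa by 2.21, C1s by 1.89, Serping1 by 1.68, C1r by 1.15 and C2 by 0.91 on the log2 scale, and Cd55, a membrane inhibitor of complement, fell by 1.29. The C1s call was lost without SNL (1.48, adjusted p = 0.101) and at the deposited scaling (1.42, adjusted p = 0.972). Not past the test were Cfd (2.02, adjusted p = 0.133), C1qc (0.70), Cfp (0.63), C4a (0.59), Cr1l (0.50), Cfi (0.23), C8b (0.17), C5ar1 (0.10), Clu (0.05), C8g (-0.01), C6 (-0.14), Masp1 (-0.55) and Cd59b (-1.47, adjusted p = 0.279), whose signal was 1446 in SNL and 154.9 in SNL with GPN and whose change turned to 0.12 without SNL with GPN. The list median was 0.59, adjusted p = 0.00116, and adjusted p = 0.69 with an estimated correlation. MHC class II presentation rose in 9 of 11 (9 adjusted over the list alone; median 1.60, adjusted p = 7.36e-09) and macrophage markers in 12 of 20 (15 adjusted over the list alone; median 1.22, adjusted p = 1.27e-08), each with adjusted p = 0.631 with an estimated correlation. The interferon list rose in 5 of 12 (7 adjusted over the list alone; median 0.79, adjusted p = 0.00227, adjusted p = 0.664 with an estimated correlation), with Gbp2 at 2.02 and Mx2 at 1.92.

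Regeneration genes rose in 13 of 28 in L6 DRG (17 adjusted over the list alone; median 0.72, adjusted p = 8.19e-08) and matrix genes in 8 of 30 (17 adjusted over the list alone; median 0.58, adjusted p = 2.9e-08). Nociceptor markers fell in 10 of 15 and 1 rose (the same adjusted over the list alone; median -1.16, adjusted p = 2.77e-08). Sodium channels fell in 4 of 9 (6 adjusted over the list alone; median -1.02, adjusted p = 1.04e-05) and potassium channels in 10 of 27 (14 adjusted over the list alone; median -0.77, adjusted p = 3.97e-08). Synaptic vesicle genes fell in 9 of 24 and 1 rose (13 and 1 adjusted over the list alone; median -0.74, adjusted p = 8.19e-08). Each of these 6 lists had adjusted p = 0.631 with an estimated correlation. Pan-neuronal markers fell in 9 of 21 and 1 rose (10 and 1 adjusted over the list alone; median -0.48, adjusted p = 1.9e-06, adjusted p = 0.69 with an estimated correlation), among them Rbfox3 (-2.02) and Nefh (-1.68). Cell cycle genes rose in 4 of 18 (7 adjusted over the list alone; median 0.59, adjusted p = 0.00451, adjusted p = 0.69 with an estimated correlation), immediate-early genes in 2 of 14 (6 adjusted over the list alone; median 0.58, adjusted p = 0.00301, adjusted p = 0.631 with an estimated correlation) and MHC class I genes in 1 of 16 (4 adjusted over the list alone; median 0.28, adjusted p = 0.0486, adjusted p = 0.75 with an estimated correlation). Glutamate receptors and transporters fell in 2 of 16 (4 adjusted over the list alone; median -0.27, adjusted p = 0.0486, adjusted p = 0.715 with an estimated correlation). The naive L6 pool held more muscle transcript (mean log2 value 7.01) than the other 4 (4.81 to 5.30). Groups were apart in 42.2% of probe sets, and the count was 86 at the deposited scaling (24 higher, 62 lower; shift of the median of all genes -0.28), 946 with no filter, 906 with muscle markers as a covariate and 2798 with 1 spread over compartments. Without naive it was 704, without naive with GPN 893, without SNL 266 and without SNL with GPN 588.

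L5 and L6 DRG shared 502 higher and 523 lower probe sets, where independence would give 49.0 and 63.2. Of the L5 calls that were also tested in L6, 95.7% of the higher and 94.8% of the lower had the same sign in L6. Probe sets called in opposite directions numbered 2. Independence of the 2 tissues is not given, since their pools came from the same groups of rats.

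**Figure D2:**
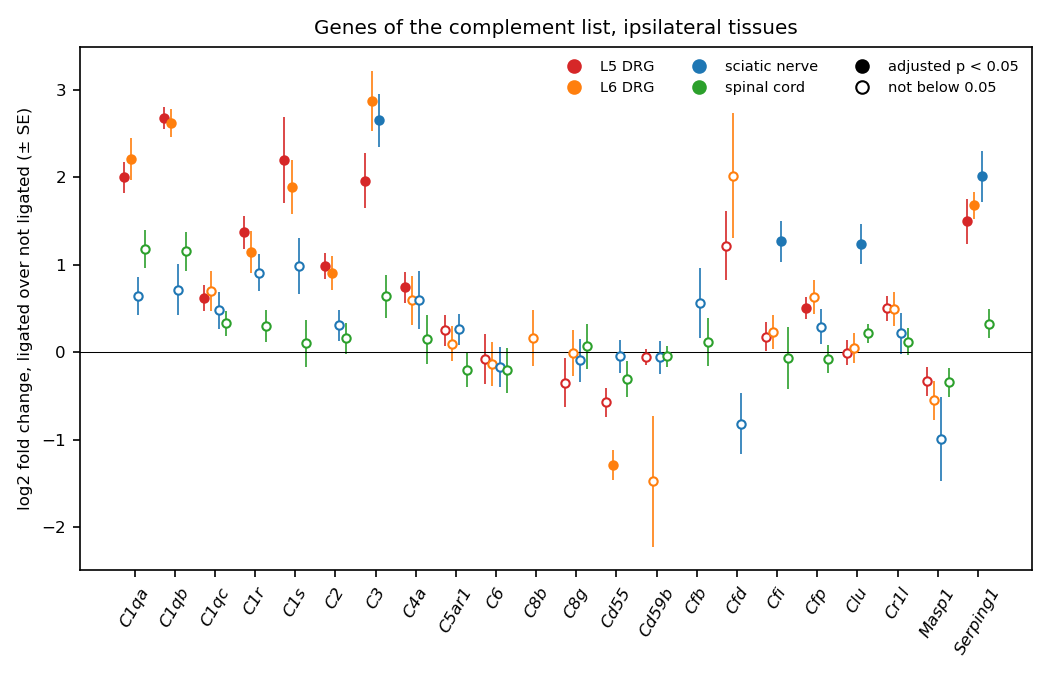
Log2 change (ligated minus not ligated, ± SE of the fit) of each tested complement gene in L5 and L6 DRG, sciatic nerve and spinal cord of the ligated side. Filled symbols have an adjusted p under 0.05, as for C3 in L5 DRG (1.96), L6 DRG (2.87) and nerve (2.65); in spinal cord 0 genes passed.

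The ipsilateral sciatic nerve was examined for changes beyond the ligation. Sema3e, an axon guidance gene, rose 13.3-fold (SE of log2 0.18, adjusted p = 0.000561), from 9.29 ± 0.462 (n = 3) to 199.5 ± 14.5 (n = 2). Ngfr, the low-affinity neurotrophin receptor of Schwann cells that have lost their axons, rose 12.6-fold from 86.3 ± 6.74 to 1159 ± 95.2, and Sox2, a marker of immature Schwann cells, rose 8.54-fold. Falls included Cnmd (9.14-fold), the metallothionein Mt3 (8.29-fold) and the collagen Col2a1 (7.92-fold). Prx, a protein of Schwann cell myelin, fell 3.26-fold, from 3619 ± 235 to 1105 ± 24.1.

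In the nerve 824 of 16925 probe sets passed, 380 higher and 444 lower, for 177 and 248 genes, and groups were apart in 38.7% of probe sets. Further rises were Nefm (3.06), Baalc (3.03), Atf3 (2.98), Dlk1 (2.76), the tubulin Tubb2b (2.68), Slc22a23 (2.68), Mpeg1 (2.66), a macrophage gene, Scn3b (2.59) and Gfra1 (2.57), a receptor for GDNF. Further falls were Fez1 (-2.76), Cdc42se2 (-2.65), Nell1 (-2.57), Cmbl (-2.47), Krt5 (-2.42), Serpina1 (-2.33) and the neurotrophic factor Cntf (-1.24). Ligated signals of Cdc42se2 (4.52), Nell1 (2.03), Cmbl (1.26), Krt5 (1.20) and Serpina1 (4.32) lay below the pseudocount, so these changes are smaller than the ratios of signals and are not ranked against that of Cnmd. Complement had 4 rises and 0 falls among 21 tested genes (5 adjusted over the list alone): C3 rose 6.28-fold (adjusted p = 0.00525), Serping1 4.02-fold, Cfi, a protease that inactivates C3b, 2.41-fold and Clu 2.35-fold. Not past the test were C1s (0.99), C1r (0.91, adjusted p = 0.0538), C1qb (0.71), C1qa (0.64), C4a (0.60), Cfb (0.56), C1qc (0.48), C2 (0.31), Cfp (0.29), C5ar1 (0.26), Cr1l (0.22), Cd55 (-0.05), Cd59b (-0.06), C8g (-0.09), C6 (-0.17), Cfd (-0.82) and Masp1 (-0.99). The list median was 0.48, adjusted p = 0.000573, and adjusted p = 0.69 with an estimated correlation. Its size moved with the setting. The median was 0.24 with the GAPDH ratio as a covariate, 0.18 with the muscle markers as a covariate and 0.24 with no filter. It was 0.26 without naive, 0.62 without naive with GPN and 0.63 at the deposited scaling.

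Lipid genes fell together in the ligated nerve. Of 18 genes of cholesterol synthesis 15 fell and 0 rose (18 adjusted over the list alone), among them Idi1 (-2.56), Insig1 (-2.30), Sqle (-2.16) and Cyp51 (-2.16), with a median of -1.53, adjusted p = 4.45e-19, and adjusted p = 0.631 with an estimated correlation. Adipocyte markers fell in 7 of 14 (11 adjusted over the list alone; median -1.36, adjusted p = 1.27e-08, adjusted p = 0.631 with an estimated correlation), with the fatty acid binding protein Fabp4 at -1.88 and Acaca, which starts fatty acid synthesis, at -1.60. Myelin genes fell in 3 of 12 (5 adjusted over the list alone; median -0.67, adjusted p = 0.000304, adjusted p = 0.69 with an estimated correlation), namely Mal (-1.91), Prx (-1.70) and Ugt8 (-1.25). Endothelial and mural markers fell in 1 of 16, Cldn5 at -1.44 (1 adjusted over the list alone; median -0.31, adjusted p = 0.0178, adjusted p = 0.69 with an estimated correlation).

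Macrophage markers rose in 3 of 21 nerve genes (5 adjusted over the list alone; median 0.40, adjusted p = 0.000147, adjusted p = 0.715 with an estimated correlation), namely Gpnmb (2.16), Lgals3 (1.80) and Fcgr2b (1.52). Regeneration genes rose in 7 of 27 (7 adjusted over the list alone, which also called 1 fall; median 0.27, adjusted p = 0.0178, adjusted p = 0.664 with an estimated correlation). Cell cycle genes had a median of 0.44 with 0 of 14 past the test over all probe sets or adjusted over the list alone (adjusted p = 0.00395, adjusted p = 0.664 with an estimated correlation). Cacna2d1 stood at -0.99 (SE 0.58, adjusted p = 0.41) and did not pass.

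The nerve samples differed in more than ligation. The GAPDH 3' to 5' ratio was 8.07 in naive, 3.96 in sham, 1.65 in naive with GPN, 1.74 in SNL and 1.72 in SNL with GPN. Muscle markers had a mean log2 value of 7.91 in naive, 7.21 in naive with GPN, 6.97 in sham, 5.10 in SNL and 7.04 in SNL with GPN, and a ligation median of -1.30 with 0 of 26 past the test, also 0 adjusted over the list alone (list adjusted p = 0.000465, adjusted p = 0.75 with an estimated correlation). Without the naive and sham nerves, which leaves 1 unligated nerve against 2 ligated and takes the spread from the ligated pair alone, 910 probe sets passed (553 higher, 357 lower; 522 of the 824 among them), with the GAPDH ratio as a covariate 159 and with the muscle markers as a covariate 5, where the median size of the 824 changes went from 1.36 to 1.30 and their median SE from 0.214 to 0.318 with residual degrees of freedom down from 3 to 2. The deposited scaling (shift of the median of all genes 0.33) gave 420 higher and 175 lower, and 1 spread over compartments 2348. Without SNL the count was 0, without SNL with GPN 190, without naive 404 and without naive with GPN 549.

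**Figure D3:**
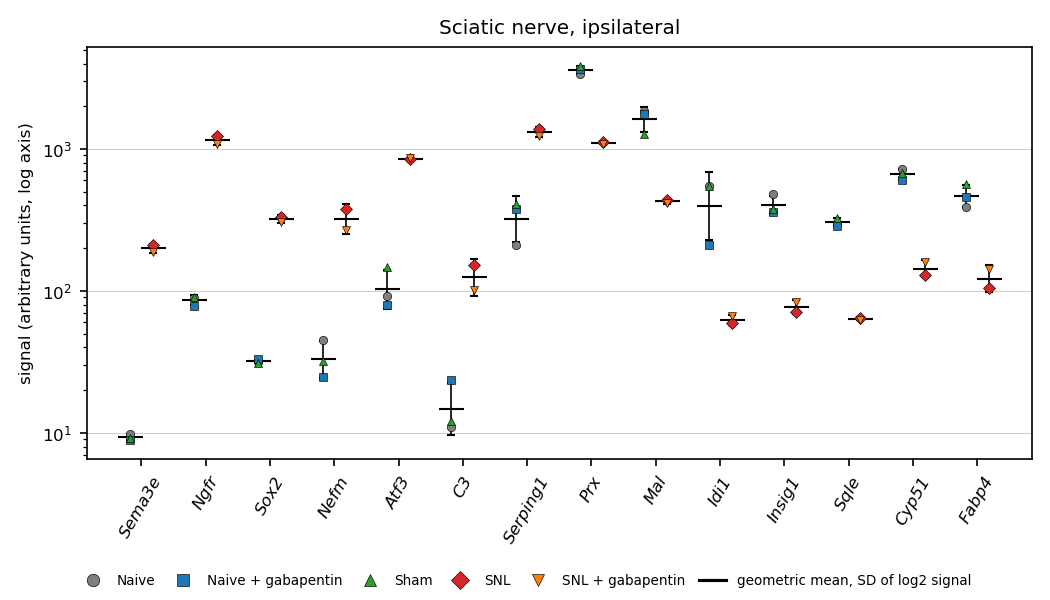
Signal (arbitrary units, log axis) of 14 genes in the sciatic nerve of the ligated side, 1 point per pool, with the geometric mean and the SD of log2 signal of each group. Ngfr lay at 1226 and 1091 in the ligated pools and between 78.6 and 91.1 in the others.

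Nerve and DRG calls overlapped. L5 DRG and nerve shared 151 higher and 113 lower probe sets, where independence would give 24.6 and 31.2, and L6 DRG and nerve shared 103 and 49 against 16.0 and 13.0. These samples too came from the same groups of rats. Of probe sets called in both L5 DRG and nerve, 32 went in opposite directions, 6 of them higher in L5 DRG and 26 lower.

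The ipsilateral L4 DRG, whose spinal nerve was intact, had 7 of 16762 probe sets past the test, 1 higher and 6 lower, each at adjusted p = 0.0467. Npy rose 6.51-fold (SE of log2 0.27), from 94.0 ± 28.0 (n = 3) to 644 ± 211 (n = 2). The named falls were the kinase gene Map2k3 (-2.30), Zranb1 (-1.92), Tbc1d22b (-1.54) and Smarcd1 (-1.45). These falls lie on array C, whose L4 medians before normalization were 53.3 in SNL and 51.8 in SNL with GPN. They were 18 in naive, 25.7 in naive with GPN and 25.6 in sham. Array brightness and ligation therefore cannot be told apart for these falls. Below the threshold of adjusted p, Vip stood at 2.36, Gal at 1.95, Cd74 at 1.46, Atf3 at 1.43 and Cacna2d1 at 1.02 (SE 0.19, adjusted p = 0.0859). Of the L5 calls, 78.5% of the higher and 79.3% of the lower had the same sign in L4, with medians of 0.20 and -0.17. MHC class II genes had a median of 0.64 with 0 of 11 past the test (7 adjusted over the list alone; list adjusted p = 1.07e-06, adjusted p = 0.631 with an estimated correlation). Regeneration genes had a median of 0.22 (0 of 25, 4 adjusted over the list alone; adjusted p = 0.000511, adjusted p = 0.631 with an estimated correlation) and complement genes 0.12 (0 of 21, 1 adjusted over the list alone, C4a; adjusted p = 0.0148, adjusted p = 0.631 with an estimated correlation). Neuropeptides had 1 rise among 17 (5 adjusted over the list alone; median 0.11, adjusted p = 0.0133, adjusted p = 0.69 with an estimated correlation). Matrix genes had a median of 0.20 (0 of 28, 1 adjusted over the list alone; adjusted p = 0.000545, adjusted p = 0.715 with an estimated correlation) and synaptic vesicle genes -0.14 (0 of 23, 2 falls adjusted over the list alone; adjusted p = 0.0204, adjusted p = 0.631 with an estimated correlation). At the deposited scaling the test direction turned and the call was lost for regeneration genes (adjusted p = 0.536), neuropeptides (0.984) and matrix genes (0.77).

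Muscle markers stood at a mean log2 value of 7.04 in the SNL pool of L4 DRG and between 4.70 and 5.39 in the other 4, with a ligation median of 0.97 and 0 of 21 past the test over all probe sets or adjusted over the list alone (list adjusted p = 0.000179, adjusted p = 0.715 with an estimated correlation). Unadjusted p was below 0.05 for 2403 L4 probe sets, where 838 would be expected, and groups were apart in 31.6%. Brightness of arrays B and C was also apart between these groups, so the excess cannot be given to ligation alone. Array B medians were 24.3 in SNL and 33.1 in SNL with GPN, against 11.4 to 20.8 in the others. The count was 0 without naive, without naive with GPN or without sham, 34 without SNL and 37 without SNL with GPN. It was also 0 with no filter, a pseudocount at the median or muscle markers as a covariate, 1 with gabapentin as a covariate, 4 without the variance trend, 62 with 1 spread over compartments, 174 at median scaling (8 higher, 166 lower; shift of the median of all genes -0.10) and 2926 at the deposited scaling (2878 higher, 48 lower; shift 0.49).

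Whether ligation acted differently on L5 and L4 DRG was tested on the difference of the 2 tissues per treatment (2 against 3). With limma, 0 of 17770 probe sets passed (lowest adjusted p 0.101; unadjusted p below 0.05 in 3529, against 888 expected). The smallest p values belonged to Ormdl1 (2.37), Qng1 (1.85), Slc43a2 (1.82), Zranb1 (1.76) and Zfp513 (1.69) on the higher side and to Hao2 (-2.40), Scn11a (-2.08), Casr (-2.02), Iapp (-1.96) and Calcb (-1.74) on the lower, none of which passed. The genes on the higher side lie on array C, whose L4 medians were 53.3 and 51.8 in ligated pools, against 18 to 25.7 in the others. Brightness of the L4 arrays cannot be told apart from ligation for them. Cacna2d1 differed by 0.83 (SE 0.26, adjusted p = 0.17). MHC class II genes differed by a median of 0.88 (0 of 11 passed, 9 adjusted over the list alone; adjusted p = 1.72e-05, adjusted p = 0.411 with an estimated correlation) and complement genes by 0.50 (0 of 21, 5 adjusted over the list alone; adjusted p = 0.0305, adjusted p = 0.411 with an estimated correlation). The pseudocount at the median gave 129 calls (21 higher, 108 lower), and the deposited scaling, with a shift of the median of all genes by -0.80, gave 4745 (63 higher, 4682 lower).

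The ipsilateral spinal cord was asked for changes where the sensory axons end. The C1q chains C1qa and C1qb stood 2.26-fold and 2.22-fold higher in ligated pools, C1qa at 460 ± 67.5 (n = 2) against 203 ± 51.1 (n = 3), and neither passed over all probe sets (adjusted p = 1.00 for both). They were the 2 of 20 tested complement genes that passed adjusted over the list alone. The other complement genes ran from C3 (0.64) over C1qc (0.33), Serping1 (0.33), C1r (0.30), Clu (0.22), C2 (0.16), C4a (0.15), Cfb (0.12), Cr1l (0.12), C1s (0.10) and C8g (0.07) to Cd59b (-0.05), Cfi (-0.06), Cfp (-0.08), C5ar1 (-0.20), C6 (-0.21), Cd55 (-0.31) and Masp1 (-0.34). The complement list had a median of 0.12 and adjusted p = 0.0241, and adjusted p = 0.642 with an estimated correlation. It missed the threshold with no filter (adjusted p = 0.113), without the variance trend (0.0562), at median scaling (0.0619), without naive (0.0522) and without sham (0.0775).

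Markers of macrophages and microglia, the resident macrophages of the cord, had a median of 0.43 in spinal cord, with 0 of 19 past the test over all probe sets or adjusted over the list alone (list adjusted p = 1.9e-06, adjusted p = 0.69 with an estimated correlation), among them Fcer1g at 0.64. The list median was 0.21 for SNL against the mean of naive and sham, and 0.66 for SNL with GPN against naive with GPN. Naive with GPN minus naive was -0.34. Smaller list medians that passed were MHC class II (0.10, adjusted p = 0.0271), regeneration genes (0.12, adjusted p = 0.00353), matrix genes (0.09, adjusted p = 0.0417), potassium channels (-0.19, adjusted p = 0.0423) and erythrocyte markers (-0.23, adjusted p = 0.0466), whose members gave 0 calls over all probe sets or adjusted over the list alone and whose adjusted p was 0.631 to 0.715 with an estimated correlation. With limma 0 of 16759 probe sets passed, and unadjusted p was below 0.05 for 454, against 838 expected. The smallest p values were those of the chemokine Cxcl13 (1.69), C1qa, C1qb, Tbc1d22b (1.24) and Fcer1g, and of Sec14l3 (-1.25), Wnt4 (-1.22), Hint2 (-1.20), Fpgs (-1.03) and Mcm10 (-0.84). Cacna2d1 stood at 0.63 (SE 0.27). The deposited scaling shifted the median of all genes by -0.14, and 1 spread over compartments gave 1 call.

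In brain 0 of 16690 probe sets passed with limma, with unadjusted p below 0.05 in 433 against 834 expected, and 0 lists passed. The smallest p values were those of Mzb1 (0.73), Prune2 (0.69), Nell1 (0.67), Chordc1 (0.57) and Polr3k (0.52) and of Fbln2 (-1.61), Gja4 (-1.31), Cdc73 (-1.31), Cebpa (-1.19) and Idi1 (-0.66), none past the test. Cacna2d1 stood at -0.36 (SE 0.19). The deposited scaling gave 7 calls (1 higher, 6 lower) and 1 spread over compartments 3.

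**Figure D4:**
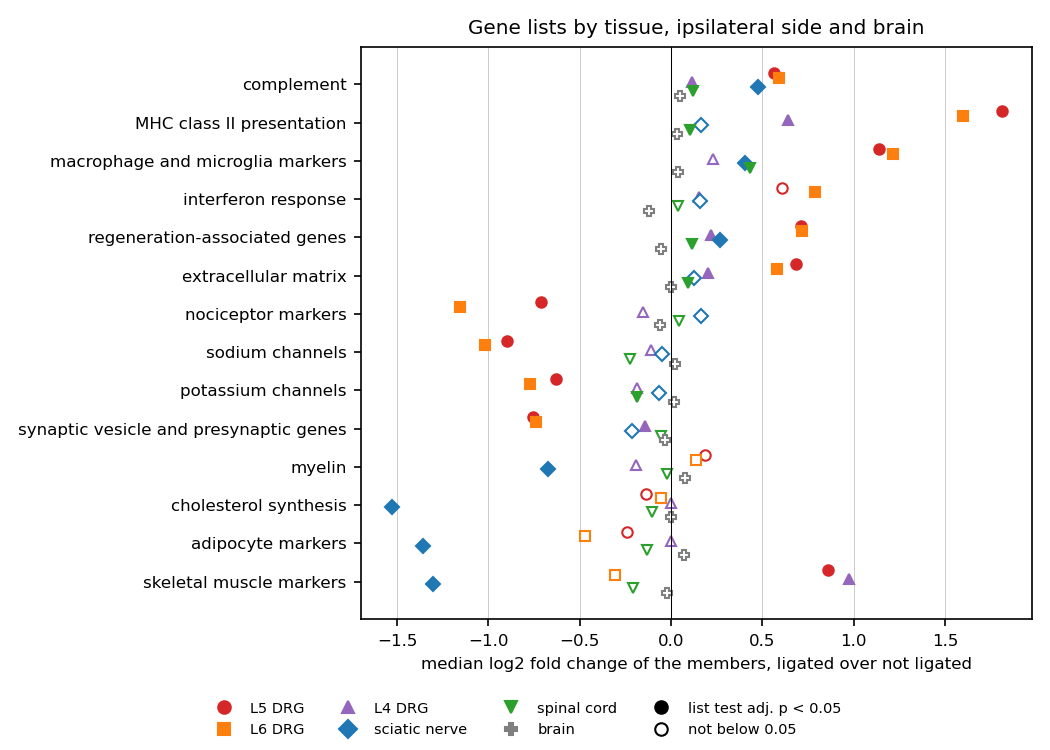
Median log2 change (ligated minus not ligated) of 14 gene lists in 6 tissues of the ligated side or brain; filled symbols have an adjusted p under 0.05 at the preset correlation, and 0 passed with an estimated correlation. Cholesterol synthesis lay at -1.53 in sciatic nerve and MHC class II presentation at 1.81 in L5 DRG.

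Contralateral tissues served as the uninjured side. In L6 DRG (2 against 2) 12 of 16450 probe sets passed, 10 higher and 2 lower, of which 2 had a gene: Bmyc (2.94, SE 0.24, adjusted p = 0.0271) and Arhgap1 (1.85, SE 0.20, adjusted p = 0.0459). Next by p, and not past the test, were Hsd3b7 (2.10), Cyba (2.00), Clk3 (1.98), Sh3gl2 (1.57) and Scarb1 (1.42), and Inhbe (-2.10), Glycam1 (-1.86), Oaz2 (-1.33), Stk39 (-1.15) and COX2 (-0.94). In L5 DRG (2 against 2) 1 of 16351 passed, a probe set with no gene name, and the named genes with the smallest p were Oaz2 (1.30), Slc14a2 (0.87), COX2 (0.86), Eef1a1 (0.81) and Scd2 (0.72), and Mapk7 (-2.01), Ubac2 (-1.94), Scarb1 (-1.68), Adcy5 (-1.59) and Tbc1d2b (-1.59). The genes named for both levels lie on array A. Its L6 medians before normalization were 19.9 (SNL) and 23.6 (SNL with GPN), against 35.9 (naive with GPN) and 55.1 (sham). In L5 they were 62.2 and 44.2 in these ligated pools, against 37.9 in naive and 32 in sham. Brightness and ligation cannot be told apart here, and Oaz2, COX2 and Scarb1 changed in opposite directions at the 2 levels. The L6 count was 1 without SNL, 1 without SNL with GPN, 5 without naive with GPN and 19 without sham, and the L5 count was 0 without any 1 pool.

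In L4 DRG 0 of 16774 and in spinal cord 0 of 16586 contralateral probe sets passed with limma, with unadjusted p below 0.05 in 672 and 834. For L4 the smallest p values belonged to Zap70 (1.15), Sord (0.99), Tbx19 (0.83), Fanca (0.79) and Elp6 (0.76) and to the clock gene Dbp (-2.39), Dhodh (-1.57), Rrm2 (-1.49), Naprt (-1.37) and Gprc5c (-1.05). For spinal cord they belonged to Dock11 (1.32), Slc27a2 (0.84), Sgk2 (0.81), Ephx2 (0.76) and Rnf157 (0.51) and to Gstk1 (-1.95), Fgf2 (-1.33), Slc39a4 (-1.14), Dbp (-0.84) and Serinc1 (-0.73). The sham L4 sample had a GAPDH 3' to 5' ratio of 3.40, against 1.02 to 1.33 in the other 4. Complement medians were 0.08, 0.02, -0.05 and 0.04 in contralateral L4, L5 and L6 DRG and spinal cord, and 0 of the 4 tests passed. The spinal cord count was 1 without naive with GPN and 2 without SNL. Spinal cord medians before normalization were apart on every array. On A they were 13 (SNL) and 27.5 (SNL with GPN), against 30.4 to 35.7 in the others. On B they were 22 and 13.1 against 26.7 to 28.3, and on C 24.7 and 22.9 against 29 to 37.1. Brightness and ligation cannot be told apart in that compartment. Cacna2d1 stood at -0.23, -0.34, -0.11 and -0.00. The deposited scaling shifted the median of all genes by 0.36, -0.37, -0.52 and -0.56 in these compartments, and gave 112 calls in L5 (86 higher, 26 lower) and 1227 in L6 (20 higher, 1207 lower).

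A few lists passed on the contralateral side. T and NK cell markers had medians of 0.32 in L4 (adjusted p = 0.0264, adjusted p = 0.69 with an estimated correlation), 0.34 in L5 (0.0486, adjusted p = 0.715 with an estimated correlation) and -0.61 in L6 DRG (0.0264, adjusted p = 0.69 with an estimated correlation), with 0 members past the test and 1 rise in L4 and 2 falls in L6 adjusted over the list alone. Erythrocyte markers in L5 DRG had a median of -0.50 (0 of 6, 5 falls adjusted over the list alone; adjusted p = 0.000565, adjusted p = 0.647 with an estimated correlation). Matrix genes in L4 DRG had a median of 0.16 (0 of 26, 0 adjusted over the list alone; adjusted p = 0.000465, adjusted p = 0.715 with an estimated correlation). In L6 DRG neuropeptides had a median of -0.28 (adjusted p = 0.00265, adjusted p = 0.69 with an estimated correlation), calcium channels -0.31 (adjusted p = 0.0291, adjusted p = 0.715 with an estimated correlation) and astrocyte markers 0.32 (adjusted p = 0.0237, adjusted p = 0.715 with an estimated correlation). Of their 17, 10 and 14 members 0 passed, and adjusted over the list alone 0, 1 fall and 1 rise were called.

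The ipsilateral and contralateral effects were compared on the difference of the sides per treatment. For L5 DRG (2 against 2) 0 of 17570 probe sets passed with limma (lowest adjusted p 0.236; unadjusted p below 0.05 in 2820, against 878 expected), and groups were apart in 50.2% where chance gives 33.3%. Genes with the smallest p were Postn (2.15), Atp2b4 (1.96), Ets1 (1.88), Polm (1.82) and the neuropeptide precursor Vgf (1.58), and Ces1c (-2.65), Galnt16 (-1.83), Kcng1 (-1.55), Lingo1 (-1.37) and Spp2 (-1.36), none past the test. Contralateral L5 medians of array A were 62.2 and 44.2 in ligated pools, against 37.9 and 32 in the others. On B they were 24.5 and 26.1 against 26.3 and 42.8, and on C 23.8 and 16.5 against 30.2 and 30.9. Brightness and ligation cannot be told apart for these genes or for the lists of this difference. Cacna2d1 differed by 2.21 (SE 0.33, adjusted p = 0.236). Complement genes differed by a median of 0.65 (0 of 20, 2 adjusted over the list alone; adjusted p = 0.00244, adjusted p = 0.557 with an estimated correlation) and MHC class II genes by 1.66 (0 of 11, 10 adjusted over the list alone; adjusted p = 1.38e-06, adjusted p = 0.444 with an estimated correlation). For spinal cord 0 of 17676 passed (lowest adjusted p 0.775; 938 unadjusted), with Tmem64 (1.86), Tmem179b (1.67), Slc39a4 (1.37), Phf12 (0.99) and Rps27 (0.86) and Clspn (-2.29), Nsun5 (-1.71), Ephx2 (-1.23), Tbrg4 (-1.15) and Rom1 (-0.94) smallest by p. Cacna2d1 differed there by 0.64 (SE 0.26, adjusted p = 0.908). Macrophage and microglia markers differed by 0.40 (0 of 19, 0 adjusted over the list alone; adjusted p = 0.00418, adjusted p = 0.444 with an estimated correlation). Brightness of the contralateral cord arrays was apart by ligation, so it cannot be told apart from ligation in this difference. The deposited scaling gave 76 calls for L5 DRG (29 higher, 47 lower) and shifted the median of all genes for spinal cord by 0.39.

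The gabapentin comparison asked which transcripts differed between the 2 treated and 3 untreated pools, with ligation as a covariate. In L5 DRG 0 of 16746 probe sets passed with limma (631 at an unadjusted p below 0.05, 837 expected), in sciatic nerve 0 of 16925 (467) and in spinal cord 0 of 16759 (523). Means over 8 compartments per pool gave 0 of 20370 (513). Cacna2d1 differed by 0.02 in L5 DRG (95% interval -0.31 to 0.34), -0.57 in nerve (-1.95 to 0.82), 0.43 in spinal cord (-0.18 to 1.03) and 0.02 over the pool means (-0.21 to 0.25). The L5 count was 8 and the pool mean count 6 without naive, and the deposited scaling gave 1 call in nerve.

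None of the genes with the smallest gabapentin p passed. In L5 DRG they were Col4a3 (1.14), Tomm5 (0.76), Lin7c (0.74), Smyd2 (0.71) and Gnai1 (0.57), and Ghr (-1.81), Gpsm2 (-1.54), the neutrophil defensins RatNP-3b (-1.30) and Defa5 (-1.14), and Svep1 (-1.09). In nerve they were Orai1 (1.56), Hipk3 (1.46), Aldoa (1.18), Sgk1 (1.00) and Tle4 (0.81), and Cyp24a1 (-1.14), Phf14 (-1.09), Epb41 (-0.98), Nufip2 (-0.96) and Prpf39 (-0.88). In spinal cord they were Myl9 (2.04), Rasa4 (1.78), Calcb (1.45), Ctsc (1.45) and Gorasp1 (1.39), and Sgca (-1.28), Csn3 (-1.28), Stk39 (-1.17), Tbxa2r (-1.01) and Ugt2b (-0.87). Over pool means they were Mef2c (0.58), Agtr1b (0.53), Gpam (0.48), Nfkbia (0.41) and Gnai1 (0.41), and Usp3 (-0.70), Slit3 (-0.51), Gcnt3 (-0.51), Cybrd1 (-0.48) and Gcm1 (-0.47).

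Granulocyte and mast cell markers had a gabapentin median of -0.50 in L5 DRG (0 of 8, 3 falls adjusted over the list alone; adjusted p = 0.000345, adjusted p = 0.988 with an estimated correlation). Matrix genes had a median of -0.13 (adjusted p = 0.00825) and erythrocyte markers -0.26 (adjusted p = 0.0203) in L5 DRG, and erythrocyte markers 0.79 in nerve (adjusted p = 0.0245), with 0 of 30, 6 and 6 members past the test, also 0 adjusted over the list alone, and adjusted p = 0.988 with an estimated correlation. The erythrocyte median turned to 0.08 in L5 DRG without naive with GPN, and to -0.11 in nerve without SNL and without SNL with GPN. Muscle markers had a median of 0.92 in nerve (0 of 26, 0 adjusted over the list alone; adjusted p = 3.93e-06, adjusted p = 0.988 with an estimated correlation), and -0.11 without SNL and -0.11 without SNL with GPN, where their sign turned. Over pool means 6 lists passed with medians between -0.18 for muscle and 0.11 for sodium channels, 0 members past the test and adjusted p = 0.988 with an estimated correlation. Among them the muscle median turned to 0.05 without naive, and the matrix median of -0.05 to 0.01 without SNL and without SNL with GPN and to 0.11 at the deposited scaling.

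Whether gabapentin moved ligation calls back towards the unligated level was read from the SNL with GPN pool against the SNL pool, 1 pool each, with no test. Signed so that values below 0 point against the ligation change, the median was -0.06 over the 2617 L5 DRG calls (60.5% below 0), -0.12 over the 1451 L6 calls (63.4%) and -0.08 over the 824 nerve calls (63.3%). The median ligation changes were 0.82, 1.14 and 1.36. The same difference between naive pools with and without GPN was 0.02, -0.03 and -0.00. The median in L5 DRG turned to 0.04 at the deposited scaling, and that in nerve went to -0.66. The complement median of SNL against the mean of naive and sham was 0.70 in L5 DRG, 0.61 in L6 DRG, 0.16 in L4 DRG, 0.71 in nerve and 0.10 in spinal cord. That of SNL with GPN against naive with GPN was 0.49, 0.66, 0.18, 0.28 and 0.11. Taken directly, SNL with GPN minus SNL had complement medians of -0.20, -0.26, -0.22, -0.13 and 0.02, an order of tissues unlike that of the other values. Such falls were not particular to complement. In L6 DRG macrophage markers stood at -0.32 and MHC class II genes at -0.30. Matrix genes stood at -0.28 in L5 DRG and -0.31 in L4 DRG, and MHC class II genes at -0.27 in nerve. Some lists went the other way, such as myelin genes in L6 DRG (0.57). In nerve the GAPDH ratio of naive (8.07) and sham (3.96) was unlike that of naive with GPN (1.65), and naive with GPN minus naive had a complement median of 0.25.

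Sham surgery was represented by 1 pool per compartment, so its difference from naive has no replicates and no test. In L5 DRG 3.0% of probe sets differed over 2-fold between sham and naive, 3.03% between naive with and without GPN, and 10.9% between SNL and naive. The corresponding shares were 4.96%, 3.86% and 11.3% in L6 DRG, 3.47%, 3.16% and 5.84% in L4 DRG, 7.01%, 6.08% and 12.1% in sciatic nerve, and 5.35%, 7.15% and 5.18% in spinal cord. In brain they were 4.20%, 3.91% and 4.09%. In spinal cord and brain sham differed from naive in a larger share than SNL did. Sham minus naive gave MHC class II genes a median of 0.47 in L5 DRG and 0.72 in nerve, macrophage markers 0.20 and 0.68, and complement genes 0.21 and 0.31. In nerve, naive with GPN minus naive, without surgery, gave these lists 0.34, 0.11 and 0.25. The GAPDH ratio of the nerves was 8.07 in naive and 3.96 in sham, so the nerve differences cannot be given to surgery.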

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

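The tests of RNA integrity, muscle and Npy below were chosen before their results were seen, and the tests of fat tissue and with the GAPDH ratio as a covariate after. The flagged results are gene lists whose ligation effect differed between tissues in a test of the difference itself. Every one was lost with an estimated correlation, where adjusted p ran from 0.411 to 0.557.

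Between L5 and L4 DRG of the ligated side, the median difference was 0.50 for complement, 0.88 for MHC class II presentation, 0.72 for macrophage markers, 0.47 for regeneration genes, 0.51 for extracellular matrix and 0.37 for immediate-early genes. It was -0.61 for neuropeptides, -0.68 for nociceptor markers, -0.59 for sodium channels, -0.38 for potassium channels, -0.41 for synaptic vesicle genes and -0.44 for pan-neuronal markers. At the deposited scaling the tests for neuropeptides (adjusted p = 0.479) and potassium channels (adjusted p = 0.692) turned direction and were lost. Brightness of arrays B and C in L4 DRG was apart by ligation, so for their genes it cannot be told apart from ligation.

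Between ipsilateral and contralateral L5 DRG, the median difference was 0.65 for complement, 1.66 for MHC class II presentation, 0.31 for MHC class I presentation, 1.11 for macrophage markers, 0.83 for the interferon list, 0.66 for regeneration genes, 0.68 for extracellular matrix, 0.61 for erythrocyte markers and 0.52 for immediate-early genes. It was -0.82 for neuropeptides (mean 0.05), -0.88 for nociceptor markers, -0.79 for sodium channels, -0.60 for potassium channels, -0.60 for synaptic vesicle genes and -0.43 for pan-neuronal markers. Between the sides of the spinal cord it was 0.40 for macrophage and microglia markers, 0.19 for regeneration genes and -0.34 for skeletal muscle markers. In contralateral L5 DRG and spinal cord, array brightness was apart by ligation. It cannot be told apart from ligation in the differences between sides.

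The calls in the ligated sciatic nerve were weighed against RNA integrity and muscle content. Over 549 probe sets called against naive and sham alone, the naive nerve with GPN, whose GAPDH ratio was near that of the ligated nerves, lay at a median position of 0.0691 (quartiles -0.115 and 0.253) between naive and sham (0) and ligated (1), which argues against RNA integrity but rests on 1 nerve. With the GAPDH ratio as a covariate, fitted over all 5 nerves, the called changes kept 1.01 of their size (quartiles 0.919 and 1.08). Calls went from 824 to 159 as the median SE grew from 0.214 to 0.258 and a degree of freedom was lost. Only 1 unligated nerve, naive with GPN (1.65), had a ratio near the ligated nerves (1.74 and 1.72). Naive stood at 8.07 and sham at 3.96. The fit therefore rests largely on that same nerve, and the 824 were called from these nerves, so it cannot exclude RNA integrity. With muscle markers as a covariate the called changes kept 0.955 of their size (quartiles 0.876 and 1.03). Calls went from 824 to 5 as the median SE grew from 0.214 to 0.318 and residual degrees of freedom fell from 3 to 2. Muscle means differed between the ligated nerves, 5.10 in SNL and 7.04 in SNL with GPN. Probe sets that followed muscle would differ between these pools and would hardly be called. The kept size was thus largely fixed by the selection and cannot exclude muscle as a cause. Without the SNL nerve the count was 0.

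The fall of cholesterol synthesis genes in that nerve was weighed against fat tissue and RNA integrity. Fat cell genes that are not lipid synthesis enzymes had a median of -0.816 (7 genes, quartiles -1.37 and -0.688), against -1.53 for 18 cholesterol genes (quartiles -1.99 and -1.25), so less fat tissue and a fall within nerve cells cannot be told apart. Over the cholesterol genes the naive nerve with GPN lay at -0.0777 (quartiles -0.252 and 0.0989). With the GAPDH covariate these genes kept 1.03 of their size (quartiles 0.94 and 1.03, median SE from 0.193 to 0.25). Past the threshold stayed 6 of 18, against 15. Both values rest largely on this 1 unligated nerve with a GAPDH ratio near the ligated nerves, so they cannot exclude RNA integrity as a cause.

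The rise of Npy in L4 DRG was weighed against RNA of injured ganglia in the L4 samples. Npy reached 29.0% of its L5 rise in L4, which is 1.74 times the median of 16.7% (quartiles 10.9% and 24.0%) over the 20 other genes with the largest L5 rise. By the rule written beforehand a ratio under 2 fits such RNA, so the rise of Npy could come from injured ganglia. Against it, Slpi (-0.816%) and Gpnmb (-2.51%) showed no rise in L4. No test separated this from a response of L4 neurons.

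Among the 10 ways to split the 5 pools into 2 and 3, the real split alone (1) called as many probe sets as it did in L5 DRG (2617), in L6 DRG (1451) and in sciatic nerve (824), and the highest other count was 0 in each. These are too few splits for a test.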

How the results depend on the processing

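The tests with median scaling, without naive and sham nerves, and with the GAPDH ratio or muscle markers as covariates were chosen after the data were seen. Of the gene results under alternatives, 5170 kept direction and side of the threshold, 782 were weaker, 67 stronger and 68 reversed. Without SNL, 56 of 93 named calls were kept in L5 DRG, 35 of 68 in L6 DRG and 0 of 60 in nerve. With an estimated correlation 0 lists passed in any family. Over the other settings 1018 list results kept both, 153 were weaker and 15 reversed; without SNL 68 of 99 list calls were kept, 27 lost and 4 reversed, and at the deposited scaling 76 were kept, 17 lost and 6 reversed. Where 1 pool, or the naive and sham nerves, were left out an arm then held in some settings a lone sample, assumed to vary like the others. With no filter on low signals the L5 DRG count was 1940, against 2617. The cause of the changes below was not tested.

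Counts of calls were, with a pseudocount at the 5th percentile, 6 in contralateral L6 DRG; at the median, 0 in L4 DRG, 7 in contralateral L6 DRG and 129 for L5 minus L4. With no filter they were 946 in L6 DRG and 0 in L4 DRG and contralateral L5 and L6 DRG. Without the trend they were 4 in L4 DRG and 0 in contralateral L5 and L6 DRG. With gabapentin as a covariate they were 1 in L4 DRG, 0 in contralateral L5 and 49 in contralateral L6 DRG. With 1 spread over compartments they were 2798 in L6 DRG, 62 in L4 DRG, 2348 in nerve, 1 in spinal cord, 3 in brain, and contralaterally 20 in L5 DRG, 28 in L6 DRG and 1 in spinal cord. At median scaling they were 174 in L4 DRG and contralaterally 0 in L5 and 2 in L6 DRG. The GAPDH covariate gave 159 in nerve, and the muscle covariate 906 in L6 DRG, 0 in L4 DRG and 5 in nerve.

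The deposited scaling gave 86 calls in L6 DRG, 2926 in L4 DRG, 7 in brain, contralaterally 112 in L5 DRG, 1227 in L6 DRG and 2 in spinal cord, 4745 for L5 minus L4, 76 for ipsilateral minus contralateral L5 DRG, and 1 for gabapentin in nerve. Gabapentin against the ligation change was 0.038 in L5 DRG and -0.66 in nerve. List tests turned direction in L4 DRG for regeneration genes (0.26), neuropeptides (0.022) and matrix (0.25), for L5 minus L4 in neuropeptides (-0.65) and potassium channels (-0.39), and for matrix in gabapentin pool means (0.11). Genes that turned sign were Cfi (-0.26) and Psme2 (-0.17) in L5 DRG; Clu (-0.16), C8b (-0.23), C5ar1 (-0.40) and Cfi (-0.23) in L6 DRG; C8g (0.28), C6 (0.21) and Cd55 (0.41) in nerve; and in spinal cord Cd59b (0.10), C2 (-0.17), C8g (-0.24) and Cfb (-0.083). Contralaterally they were Cacna2d1 in L4 (0.094) and L5 DRG (0.073) and Rnf157 (-0.33) and Ephx2 (-0.049) in spinal cord.

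The complement list in spinal cord missed the threshold with no filter (median 0.10, adjusted p = 0.113), without the trend (median 0.12, adjusted p = 0.0562), at median scaling (median 0.18, adjusted p = 0.0619), without naive (median 0.094, adjusted p = 0.0522), without sham (median 0.080, adjusted p = 0.0775) and with an estimated correlation (median 0.12, adjusted p = 0.642). The estimated correlation also ended it in L5 DRG (median 0.56, adjusted p = 0.69) and nerve (median 0.48, adjusted p = 0.69). Other signs that turned were Cacna2d1 in contralateral spinal cord with a pseudocount at the median (0.00053); at median scaling C8g in L6 DRG (0.012), Cd59b in spinal cord (0.18), and Cacna2d1 in contralateral L6 DRG (0.11) and for gabapentin in L5 DRG (-0.0037); without naive and sham nerves Cacna2d1 (0.12), Cd59b (0.15), C4a (-0.046) and Cd55 (0.079); with the GAPDH covariate in nerve Cacna2d1 (0.063), Cd59b (0.10), Cfb (-0.10) and Cd55 (0.12); and with the muscle covariate C6 in L5 DRG (0.25), C8g in L6 DRG (0.027), and Cd59b (0.092) and Cd55 (0.16) in nerve.

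Leaving out each pool in turn, counts ran from 768 to 1899 in L5 DRG, 266 to 1426 in L6 DRG, 0 to 37 in L4 DRG, 0 to 1006 in nerve, 0 to 0 in contralateral L5 DRG, 1 to 19 in contralateral L6 DRG, 0 to 2 in contralateral spinal cord, 0 to 8 for gabapentin in L5 DRG and 0 to 6 for its pool means. List medians ran from 0.080 to 0.15 for complement in spinal cord, -0.12 to 2.17 for muscle in L4 DRG, and for gabapentin from -0.52 to 0.083 (erythrocyte, L5 DRG), -0.11 to 2.02 (muscle, nerve), -0.11 to 1.94 (erythrocyte, nerve), -0.14 to 0.0054 (matrix, pool means) and -0.33 to 0.045 (muscle, pool means).

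Gene values over the same settings ran, in L5 DRG, from -0.13 to 0.089 for Clu, -0.10 to 0.0014 for Cd59b and -0.39 to 0.24 for C6. In L6 DRG they ran from -0.18 to 0.27 for Clu, -3.06 to 0.12 for Cd59b, -0.066 to 0.43 for C8b, -0.051 to 0.25 for C5ar1 and -0.11 to 0.092 for C8g. In nerve they ran from -0.18 to 0.063 for Cd59b, -0.22 to 0.045 for C8g and -0.15 to 0.064 for Cd55. In spinal cord they ran from -0.28 to 0.48 for C1s, -0.13 to 0.019 for Cd59b, -0.10 to 0.19 for Cfi, -0.014 to 0.33 for C2, -0.083 to 0.30 for Cfb and -0.038 to 0.40 for C4a. Cacna2d1 ran from -0.22 to 0.21 in contralateral spinal cord and -0.46 to 0.24 in contralateral L6 DRG, and for gabapentin from -0.052 to 0.065 in L5 DRG, -1.66 to 0.89 in nerve and -0.12 to 0.21 over pool means.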

Other observations

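The values given here were picked out after the results were seen, and the tests behind the gene calls were not. In L6 DRG further neuropeptide genes moved with ligation: Cck (1.75), Vgf (1.54) and Cartpt (1.19) rose, and Nmb (-1.79), Crh (-1.78), Tac1 (-1.70), which encodes substance P, and Calcb (-1.70) fell. In L5 DRG Vgf rose (1.48), and Nmb (-1.30), Chgb (-1.29), Calcb (-1.16), Scg2 (-1.13), Calca (-0.65) and Tac1 (-0.59) fell.

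Over the 824 probe sets called in the ipsilateral nerve, the contralateral nerve of the SNL pool with GPN lay at a median of -0.03, signed to the ligation change, and the other contralateral nerves between -0.04 and 0.07. Of 845 further probe sets of genes called in L5 DRG, 777 had the same sign as the named one, as had 449 of 488 in L6 DRG and 265 of 285 in nerve. Atp1b3, Atp2a2 and Klc1 had probe sets called in opposite directions in L5 DRG.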
